A study of Mus musculus with 75 samples.

How the data were processed

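RNA sequencing libraries of mouse cerebral cortex, hippocampus and NeuN-sorted cortical neuron nuclei, all at postnatal day 21, were analysed. Of the 75 samples of the series, 26 RNA libraries in 10 groups were used. The other 49 samples, of chromatin immunoprecipitation and DNA methylation, were not analysed here.

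Per the labels' protocols, the nuclei were freed from cortex by douncing and sorted with an antibody against NeuN, and the RNA libraries were made with a stranded mRNA kit. Per the labels, reads were aligned to mouse genome build mm9 with STAR 2.5.4a and assigned to genes with HTSeq 0.11.0. The deposited values are counts, whole numbers of reads per gene, with no normalization recorded and 1 library per file. Neither the annotation release nor the strand setting of the counting is stated in the sources used here, so a gene and an overlapping or antisense gene may share reads. The cortex and nuclei files list 37310 gene identifiers, 32620 of which were given a symbol from the supplied name table. The hippocampus files list 55487 identifiers, another and larger annotation, 55394 of which were given a symbol, and 32601 identifiers were shared. Comparisons across tissues used the shared identifiers only. No mm9 annotation with coordinates was used, so positions are not given and a planned test of a trend with gene length was not run.

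Gene totals per library ran from 8.7 to 39.0 M counts (M, mega). Between 21.14% and 36.97% of reads fell in lines of the files that name no gene (no feature, ambiguous, not aligned or not unique). Averaged over genes, differences between replicates of a group exceeded counting noise in each pair compared. Genes with many counts weigh most in this average, so read depth can still limit the precision for genes with few counts. Nothing in the labels says whether libraries of a group came from separate animals, so p-values measure only the spread between these libraries. By Xist and Y-linked reads each group held 1 female and 1 or 2 male libraries, so each came from more than 1 animal. Whether 2 male libraries of a group came from separate males stays open.

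The labels do not tie the 8 wild type cortex libraries to a mutant. Their titles carry 3 numbering series: plain numbers, numbers with r and numbers with n. The plain series was taken, before the data were examined, as control of Dnmt3a1-/-, the r series of Dnmt3a2-/- and the n series of Dnmt3a1_delta_N, with all 8 libraries as an alternative. Gene counts were compared with edgeR 4.0.16 (R 4.3.3): genes were filtered with filterByExpr, scaled by TMM, fitted with a robust quasi-likelihood model with one mean per group and tested with the quasi-likelihood F-test. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Fold changes are log2 of mutant over wild type with their standard error (SE), and counts per M (CPM) are given as mean and standard deviation (SD). The SE was derived from the test, as the size of the log2 fold change over the square root of the F statistic. Differences between 2 effects were tested as the interaction contrast in the same model.

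A total of 33 gene lists of pathways, gene families and cell type markers, with 1158 genes, were written at the same time. Each list with at least 5 tested members was tested in each comparison with camera of limma 3.58.1, two-sided, on log2 CPM with a preset correlation between genes of 0.01, and adjusted over the lists of that comparison. The test was repeated with a correlation estimated from the data and with fry, which asks whether the members move one way on balance and does not compare them with other genes. All 54 list calls were lost with an estimated correlation, and fry kept 6 of the 54. List members past the test are counted over all genes and adjusted over the list alone. The genes called higher and the genes called lower in cortex Dnmt3a1-/- were also tested as sets in the other comparisons.

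Genes were named by a rule also fixed then: Dnmt3a first, then per comparison up to 10 called genes with the largest change in each direction, with a mean log2 CPM of at least 1 and no overlap between mutant and wild type libraries, then up to 4 called members per list. Where none qualified, the 3 genes with the smallest p in each direction were taken. For differences of effects, up to 5 genes per direction were taken. Symbols of predicted genes were left out, and some genes that the rule names are not reported here.

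Same-numbered libraries were checked for pairing by the correlation, across genes, of their deviations from the group means. It was 0.182, 0.141 and 0.125 in cortex Dnmt3a1-/- and 0.334, 0.178 and 0.25 in Dnmt3a1_delta_N, each over 0.1, so the numbers were taken to pair the libraries there. Differently numbered libraries correlated at -0.124 to 0 in cortex Dnmt3a1-/- and -0.229 to -0.009 in Dnmt3a1_delta_N. The pairing comes from these values alone, not from the labels. The main fits left this pairing out, and the alternative with the replicate number as a block is the fit that models it. Same-numbered libraries were also of the same sex by Xist and Y-linked reads. In hippocampus the values were -0.098, 0.113 and -0.02, so the numbers were not taken as pairs. A differently numbered pair of hippocampus libraries reached 0.119, close to the lowest value taken as a pair in cortex Dnmt3a1-/-, so that pairing is uncertain. Same-numbered libraries stood at -0.112 in Dnmt3a2-/- and 0.125 in nuclei, where groups of 2 libraries were too few for a decision on pairing. Between hippocampus and cortex same-numbered libraries correlated at 0.26, 0.135 and 0.216 in wild type and 0.082, 0.115 and 0.118 in Dnmt3a1-/-, and the comparison of tissues did not model this.

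Alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter beyond 1 count, a mean CPM of at least 1, a 1.5-fold minimum, the replicate number as a block, sex as a term, all 8 wild type cortex libraries, and each library left out in turn. A choroid plexus score (the mean log2 CPM of choroid plexus markers) as a covariate and a block with crossed numbers in Dnmt3a2-/- were added after the data were seen.

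Each step was tested on simulated counts drawn from the means and library sizes of these libraries, with 200 genes changed by known folds. Of the genes changed 1.5-fold, 79.1% were recovered in the simulated cortex Dnmt3a1-/- comparison (15933 genes), 61.2% in Dnmt3a2-/- (15929), 85.1% in Dnmt3a1_delta_N (15881), 65.7% in hippocampus (15727) and 23.9% in nuclei (15860). Of the genes changed 2-fold, 91.0% to 100% were recovered in these 5 comparisons. For the difference of effects between Dnmt3a1_delta_N and Dnmt3a1-/- (16456 genes) recovery was lower, 47.8% at 1.5-fold and 74.6% at 2-fold, and the other differences of effects were not simulated. Unchanged genes made up 3.9% to 14.6% of the simulated calls, the highest share in the Dnmt3a2-/- design, so more than the nominal share of calls can be false in some of these designs. The simulated genes varied independently and without pair effects, so these shares are not the power of the real fits. In Dnmt3a1_delta_N Myl4, close to 2-fold lower, did not pass the main fit. Few calls in a comparison therefore do not exclude 2-fold changes there.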

Results

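Messenger RNA was measured in brains of mice with altered DNMT3A, an enzyme that adds methyl groups to cytosines of DNA. The gene makes a long isoform, DNMT3A1, and a short one, DNMT3A2, that lacks the N-terminal part of the long one. The mutants were Dnmt3a1-/-, Dnmt3a2-/- and Dnmt3a1_delta_N, whose name states a deletion of the N-terminal part of DNMT3A1. In cortex there were 3 Dnmt3a1-/-, 2 Dnmt3a2-/- and 3 Dnmt3a1_delta_N libraries, with 8 wild type libraries in 3 numbering series of 3, 2 and 3 (plain, r and n). Hippocampus had 3 Dnmt3a1-/- and 3 wild type libraries, and sorted cortical neuron nuclei had 2 of each. In the order of their numbers, gene counts (M, mega counts) were 24.4, 26.8 and 17.8 M in the plain wild type series, 11.7, 26.2 and 26.4 M in cortex Dnmt3a1-/-, 27.6 and 32.3 M in the r series and 32.1 and 23.8 M in Dnmt3a2-/-. They were 35.6, 32.0 and 27.3 M in the n series and 25.7, 33.6 and 27.4 M in Dnmt3a1_delta_N. In hippocampus they were 8.7, 17.8 and 14.7 M in wild type and 11.4, 14.6 and 23.2 M in Dnmt3a1-/-. In nuclei they were 35.2 and 35.4 M in wild type and 39.0 and 25.3 M in the libraries labelled Dnmt3a1-/-.

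The 3 wild type cortex series differed from each other: edgeR called 5368 genes between the plain and r series, 3199 between plain and n and 4409 between r and n. The first principal component of the 16 cortex libraries carried 50.7% of the variance. It placed the plain wild type series (-44.7 to -37.4) and Dnmt3a1-/- (-56.7 to -52.4) apart from the r and n series and the other mutants (22.7 to 34.3). Each mutant was compared with 1 series, with all 8 wild type libraries as an alternative, and a difference between series and a difference between mutants cannot be told apart where the tie of series to mutant is wrong. The fit with all 8 has no term for the series, so it mixes differences between series with the effect of a mutation.

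Dnmt3a (ENSMUSG00000020661) was read at 72.5, 80.6 and 74.6 CPM in cortex Dnmt3a1-/- against 150, 165 and 148 CPM in wild type. It fell by 1.02 ± 0.07 on the log2 scale (SE, n = 3 against 3, adjusted p = 1.2e-05). In hippocampus it was read at 69.0, 75.5 and 74.2 CPM in Dnmt3a1-/- against 165, 150 and 136 CPM, and fell by 1.04 ± 0.09 (n = 3 against 3, adjusted p = 0.00011). In nuclei labelled Dnmt3a1-/- it was read at 381 and 371 CPM against 409 and 395 CPM, a log2 difference of -0.10 ± 0.15 that did not pass (n = 2 against 2, adjusted p = 0.89). The nuclei count thus did not follow the genotype label as the tissue counts did. Dnmt3a2-/- libraries held 133 and 142 CPM against 155 and 144 CPM (adjusted p = 1), and Dnmt3a1_delta_N libraries 135, 138 and 142 CPM against 145, 161 and 163 CPM (adjusted p = 0.59). Reads of exons that the isoforms share are summed in this count, so it checks the Dnmt3a2-/- and Dnmt3a1_delta_N labels little.

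**Figure D1:**
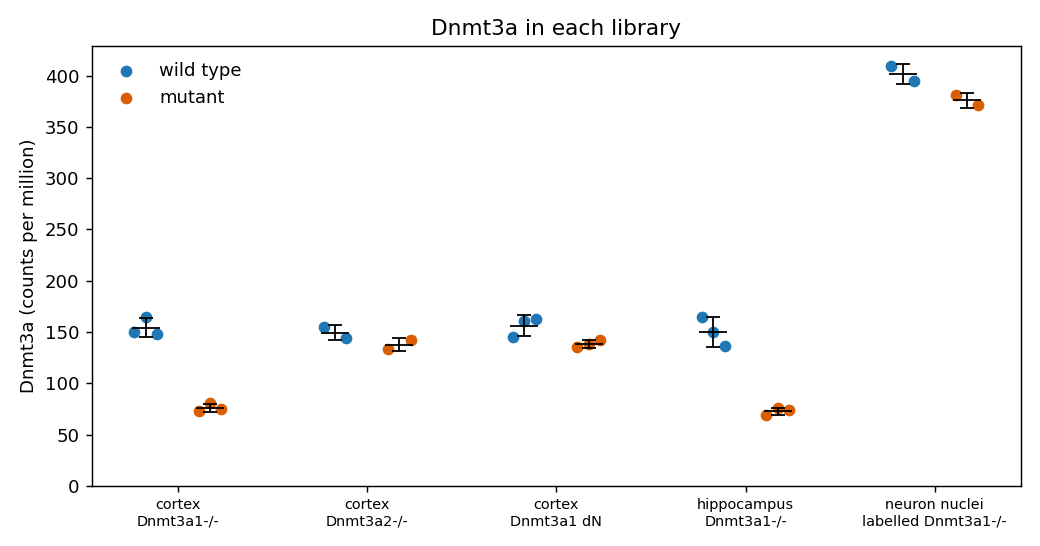
Dnmt3a in counts per M (y axis) in each library (points) of the 5 comparisons, with group means and SD (black). The Dnmt3a1-/- cortex libraries lie between 72.5 and 80.6, below their controls at 148 to 165, and the nuclei labelled Dnmt3a1-/- lie at 371 and 381 beside controls at 395 and 409.

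Loss of DNMT3A1 in cortex was compared with wild type to ask which genes depend on the long isoform. Plin4 (ENSMUSG00000002831), which codes for a coat protein of lipid droplets, rose by 3.23 ± 0.43 on the log2 scale (SE, n = 3 against 3), from 0.78 ± 0.52 to 6.55 ± 2.5 CPM (SD, adjusted p = 0.0026). Angptl4 (ENSMUSG00000002289), a secreted inhibitor of lipoprotein lipase, rose by 2.22 ± 0.18 (3.38 ± 0.69 to 15.9 ± 3.6 CPM, adjusted p = 4.8e-05). Dct, an enzyme of melanin synthesis, rose by 2.25 ± 0.21 (adjusted p = 4.8e-05), and Gpnmb, a glycoprotein of lysosomes and phagocytes, by 2.03 ± 0.16 (adjusted p = 1.3e-05). Gdf10 (ENSMUSG00000021943), a secreted ligand related to bone morphogenetic proteins, rose by 1.19 ± 0.09 (adjusted p = 1.3e-05). Among falling genes, Aplnr (ENSMUSG00000044338), the apelin receptor of growing vessels, fell by 2.02 ± 0.23 (6.28 ± 1.5 to 1.63 ± 0.5 CPM, adjusted p = 0.00025), and Pcdh12, a protocadherin of endothelium, fell by 1.93 ± 0.2 (adjusted p = 0.00011). Kcng4 (ENSMUSG00000045246), a modifying subunit of voltage-gated potassium channels, fell by 1.32 ± 0.12 (adjusted p = 4e-05). Mki67 and Top2a, genes of dividing cells, fell by 1.09 ± 0.16 and 1.05 ± 0.16 (adjusted p = 0.00068 and 0.0011). Imprinted Meg3 and Peg3 rose by 0.62 ± 0.09 and 0.49 ± 0.07 (adjusted p = 0.00085 and 0.00062), while imprinted Mest fell by 0.69 ± 0.09 (adjusted p = 0.00048).

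Of 15933 genes tested by edgeR, 2845 were called, 1426 higher and 1419 lower, and 743 of them (488 higher and 255 lower) differed at least 1.5-fold. With the replicate number as a block 4941 genes were called. Mutant and wild type libraries did not overlap for 5740 genes (36.0%), where chance gives 10% for 3 against 3. Without wild type library 3 the count was 1599, and without Dnmt3a1-/- library 2 it was 1835. With all 8 wild type cortex libraries as controls 3109 genes were called, 1964 of them among the 2845. That fit has no term for the series, so added calls can be differences between series and lost calls can come from a wider spread. With a choroid plexus score as a covariate, chosen after the data were seen, 434 genes were called, 421 of them among the 2845. The score correlated with genotype at 0.68, so the fall does not measure how much of the difference is choroid plexus.

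**Figure D2:**
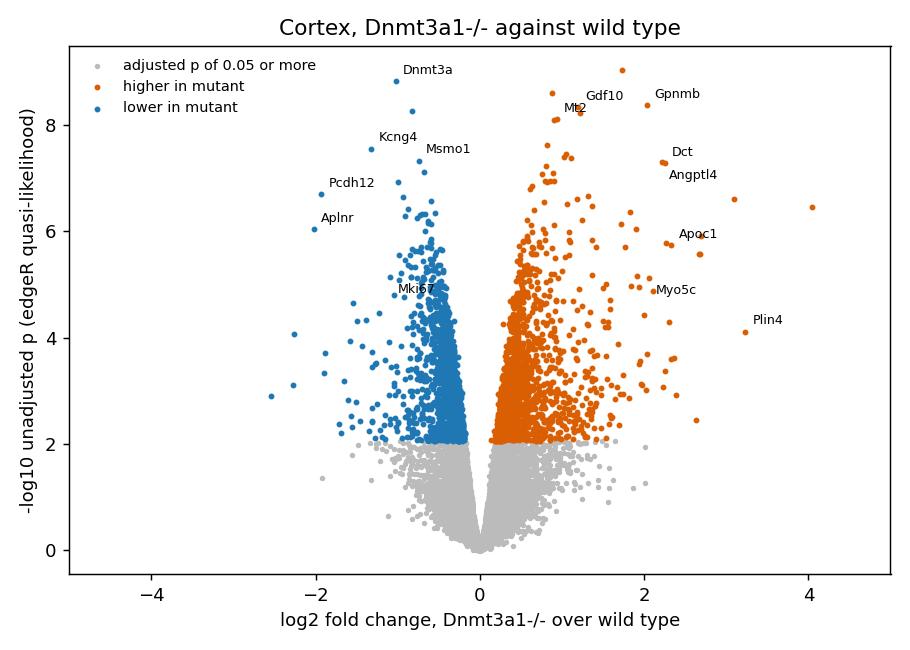
Log2 fold change (x axis, Dnmt3a1-/- over wild type) against -log10 of the unadjusted p of edgeR (y axis) for each of the 15933 genes tested in cortex. Of the 2845 coloured genes 1426 were higher and 1419 lower in the mutant, and Dnmt3a lies at -1.02 on the x axis.

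Genes of cholesterol biosynthesis were the list with the lowest adjusted p in this comparison. Of 22 tested, 18 were lower over all genes and 19 adjusted over the list alone, with a median log2 fold change of -0.51 (camera adjusted p = 2.2e-12, adjusted p = 0.38 with an estimated correlation). Msmo1, an oxidase of the pathway, fell by 0.74 ± 0.07 (adjusted p = 4.8e-05). Of 49 synaptic genes 25 were lower (31 adjusted over the list alone, beside 1 higher), with a median of -0.28 (adjusted p = 3.9e-10, adjusted p = 0.54 with an estimated correlation). Of 23 genes induced by glucocorticoids or stress, 11 were higher (15 adjusted over the list alone), with a median of 0.63 (adjusted p = 1.1e-08, adjusted p = 0.38 with an estimated correlation). Mt2, a metal-binding protein, rose by 0.94 ± 0.08 from 72 ± 2.8 to 138 ± 12 CPM (adjusted p = 1.4e-05), and Ddit4, a stress-induced inhibitor of mTOR signalling, by 0.82 ± 0.07 (adjusted p = 3.8e-05). Of 33 interferon response genes 12 were higher (17 adjusted over the list alone), median 0.29 (adjusted p = 4.8e-05, adjusted p = 0.6 with an estimated correlation). Of 19 germline genes 4 were higher (7 adjusted over the list alone), median 0.60 (adjusted p = 0.001, adjusted p = 0.38 with an estimated correlation).

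Beside these list medians, reads outside genes were 10.34% or more of uniquely aligned reads in each Dnmt3a1-/- cortex library and at most 10.16% in wild type, and the 500 genes with the highest ratio of nuclei over cortex were higher by a median of 0.29 relative to all genes. The wild type controls of this comparison helped to choose these 500 genes, which by itself shifts them up.

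Clustered protocadherins, cell surface proteins of neuronal identity, had a median of -0.48 with 6 of 23 lower and 12 adjusted over the list alone (adjusted p = 3.9e-07, adjusted p = 0.38 with an estimated correlation). Their genes share exons and resemble each other closely, so reads of single members are uncertain. Ribosomal protein genes had a median of 0.13 with 11 of 72 higher and 9 adjusted over the list alone (adjusted p = 6.8e-06, adjusted p = 0.63 with an estimated correlation). Inhibitory neuron markers had a median of -0.19 with 10 of 32 lower, also 10 adjusted over the list alone (adjusted p = 0.0017, adjusted p = 0.46 with an estimated correlation). Striatum markers had a median of -0.23 with 0 of 20 called over all genes or over the list alone (adjusted p = 0.022, adjusted p = 0.76 with an estimated correlation, and from 3.5e-06 to 0.72 with 1 library left out). Choroid plexus markers had a median of 0.71 with 0 of 22 called by edgeR, although the list passed (adjusted p = 0.001, adjusted p = 0.63 with an estimated correlation). Ttr, the most abundant of them, was read at 1910, 783 and 1140 CPM in Dnmt3a1-/- and at 483, 705 and 112 CPM in wild type. Blood markers had a median of -0.85 with 2 of 11 lower and 5 adjusted over the list alone (adjusted p = 0.0033, adjusted p = 0.54 with an estimated correlation). Markers of astrocytes, microglia, endothelium and myelin did not pass as lists, with medians of 0.11, -0.04, -0.05 and 0.04. Single members were called all the same. The called members named by the rule were all lower for microglia (Fcrls, Olfml3, Itgam and P2ry13) and endothelium (Itm2a, Slco1c1, Emcn and Pltp). For astrocytes (Agt higher, Aqp4 lower) and myelin (Mbp higher, Trf lower) they went both ways. Other called members of these lists are not counted here. Genes of the HOX clusters were not tested in any comparison, since the filter removed all of them; their pooled counts were 10 or fewer in each of these 6 libraries.

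In cortex of Dnmt3a2-/- mice 1 gene was called. Rps4l, a ribosomal protein gene with close copies whose reads are therefore uncertain, rose by 1.63 ± 0.16 on the log2 scale (SE, n = 2 against 2, adjusted p = 0.0094). With all 8 wild type libraries as controls Rps4l did not pass (1.3, adjusted p = 0.28, from 5.4e-22 to 0.28 over the alternatives), and 2 other genes were called. The genes with the smallest p among lower ones did not pass: Hivep3, a zinc finger protein, at -0.36 ± 0.1, Hmcn1, an extracellular matrix protein, at -0.56 ± 0.16, and Sgsm1, a regulator of small GTPases, at -0.34 ± 0.1 (adjusted p = 1 for each). Among 22 germline genes 0 were called by edgeR over all genes and 6 were higher adjusted over the list alone, with a median of 0.34 (adjusted p = 1.5e-05, adjusted p = 0.79 with an estimated correlation). Stk31, a germline kinase named after its values were seen, held 79 counts over the mutant libraries and 0 over wild type, at least 28.2-fold higher against a floor of 3 counts over the group (adjusted p = 0.22). With Stk31 at that bound the list median was also 0.34. Genes induced by glucocorticoids or stress had a median of 0.28 with 6 of 23 higher adjusted over the list alone (adjusted p = 3.9e-07, adjusted p = 0.79 with an estimated correlation). Interferon response genes had a median of -0.43 (adjusted p = 0.00042, adjusted p = 0.85 with an estimated correlation), but that list turned to higher without wild type r library 2 (adjusted p = 8.5e-06) and missed the threshold without Dnmt3a2-/- library 1 (adjusted p = 0.17). Choroid plexus markers had a median of 1.36 (adjusted p = 0.0043, adjusted p = 0.85 with an estimated correlation), with Ttr at 10.8 and 1500 CPM in the mutant and 258 and 18.3 CPM in wild type. That list missed the threshold without wild type r library 2 (adjusted p = 0.81) and turned to lower without Dnmt3a2-/- library 2 (adjusted p = 0.61). Of 15929 genes tested 457 had an unadjusted p under 0.05 by edgeR (338 of them higher), a smaller share than chance gives. Libraries did not overlap for 4436 genes (27.8%), where chance gives 33.3% for 2 against 2. The DESeq2 Wald test called 8, and edgeR with the replicate number as a block, not taken as pairs here, called 55. Same-numbered libraries correlated at -0.112 and differently numbered ones at 0.112. Markers of mural and meningeal cells and of striatum had medians of 0.45 and 0.35 (adjusted p = 3.2e-07 and 3.2e-06, each adjusted p = 0.79 with an estimated correlation) but missed the threshold without Dnmt3a2-/- library 2 (adjusted p = 0.37 and 0.41). Myelin markers had a median of 0.12 (adjusted p = 0.00083, adjusted p = 0.79 with an estimated correlation, and from 3.7e-05 to 0.37 with 1 library left out). Leaving out Dnmt3a2-/- library 1, library 2, wild type r library 1 or r library 2 gave 90, 139, 56 and 25 calls.

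The Dnmt3a1_delta_N mutant was compared with wild type cortex to ask what the N-terminal part of DNMT3A1 does. No gene passed by edgeR in the main fit, which left the pairing out, while the fit with the replicate number as a block called genes both ways. The smallest p among lower genes belonged to Myl4, a myosin light chain, at -0.97 ± 0.12 on the log2 scale (SE, n = 3 against 3, 27.3 to 13.9 CPM, adjusted p = 0.12, and 0.00013 with the replicate number as a block). Nr4a2, a transcription factor of the orphan nuclear receptors, stood at -0.51 ± 0.07 (adjusted p = 0.21, with the block 0.0051), and Gpr21, an orphan receptor, at -0.96 ± 0.15 (adjusted p = 0.25, with the block 0.0051). Among higher genes Gdf10 stood at 0.65 ± 0.11 (adjusted p = 0.34, with the block 0.0088), Chrd, an extracellular antagonist of bone morphogenetic proteins, at 0.40 ± 0.07 (adjusted p = 0.34, with the block 0.012), and Plch2, a phospholipase, at 0.40 ± 0.07 (adjusted p = 0.37, with the block 0.015). Myl4 also passed with sex as a term (adjusted p = 0.018).

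Of 15881 genes 0 were called by edgeR, 1267 had an unadjusted p under 0.05 (597 higher and 670 lower), and the lowest adjusted p was 0.12. The DESeq2 Wald test called 31 genes. With the replicate number as a block edgeR called 33 genes higher and 86 lower. Of the blocked calls also tested in cortex Dnmt3a1-/-, 22 of 32 higher genes were called higher there (2.92 in independent lists) and 66 of 86 lower genes were called lower (7.88 in independent lists), and 0 were called the opposite way. Libraries did not overlap for 2087 genes (13.1%), against 10% by chance. Without Dnmt3a1_delta_N library 3 the count was 2, and without wild type n library 1 it was 1.

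Of the 72 ribosomal protein genes tested in Dnmt3a1_delta_N, 72 had positive log2 fold changes and 0 were called by edgeR, with a median of 0.18 (adjusted p = 5.9e-24, adjusted p = 0.71 with an estimated correlation). Synaptic genes had a median of -0.15 (adjusted p = 2.1e-08), clustered protocadherins of -0.15 (adjusted p = 9.9e-05) and excitatory neuron markers of -0.09 (adjusted p = 0.00055), each with adjusted p = 0.71 with an estimated correlation. Markers of myelin, oligodendrocyte precursors and mural and meningeal cells had medians of 0.08, 0.12 and -0.08 with 0 members called over all genes (adjusted p = 0.0087, 0.017 and 0.0087, adjusted p = 0.71, 0.71 and 0.75 with an estimated correlation), and with 1 library left out they reached adjusted p = 0.14, 0.12 and 0.39. Immediate early genes had a median of -0.15 (adjusted p = 0.00049, adjusted p = 0.71 with an estimated correlation), with adjusted p = 0.052 without Dnmt3a1_delta_N library 1. Choroid plexus markers had a median of 0.57 that did not pass (adjusted p = 0.31, with the block 0.029), with Ttr at 905, 661 and 78.1 CPM in the mutant and 71.5, 378 and 27.2 CPM in wild type.

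Hippocampus of Dnmt3a1-/- mice was compared with wild type to ask whether a second brain region responds. Otoa, a protein of extracellular gels named for the inner ear, rose by 2.92 ± 0.19 on the log2 scale (SE, n = 3 against 3), from 1.26 to 9.4 CPM (adjusted p = 1.5e-05). Angptl4 rose by 2.08 ± 0.18 (adjusted p = 0.00011), Apoc1, an apolipoprotein, by 2.17 ± 0.26 (adjusted p = 0.0017), Dct by 2.13 ± 0.29 (adjusted p = 0.0028) and Wnt10b, a secreted Wnt ligand, by 1.87 ± 0.31 (adjusted p = 0.0079). Plin4 rose by 2.60 ± 0.51 and passed narrowly (adjusted p = 0.049, and 0.053 with DESeq2 size factors). Aplnr fell by 1.5 ± 0.26 (adjusted p = 0.01), Kcng4 by 0.94 ± 0.13 (adjusted p = 0.0031), and Olfml3, a secreted protein of microglia, by 0.89 ± 0.13 (adjusted p = 0.0043). Aqp4, the water channel of astrocytes, fell by 0.68 ± 0.11 (adjusted p = 0.0073) and in cortex by 0.51 ± 0.08 (adjusted p = 0.0009).

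Of 15727 genes 396 were called in hippocampus by edgeR, 266 higher and 130 lower, and 204 of them (158 higher and 46 lower) differed at least 1.5-fold. The DESeq2 Wald test called 597, 307 higher and 290 lower, so the share of higher genes was 51.4% rather than 67.2%. No filter beyond 1 count gave 1039 genes, and the replicate number as a block, not taken as pairs here, 246 (187 higher and 59 lower). Libraries did not overlap for 3679 genes (23.4%), against 10% by chance. The count depended on single libraries: it was 86 without Dnmt3a1-/- library 2, 220 without Dnmt3a1-/- library 3, 783 (354 higher and 429 lower, so the excess of higher genes turned) without wild type library 1, 137 without wild type library 2 and 172 without wild type library 3. With a choroid plexus score as a covariate, chosen after the data were seen, 202 genes were called, 174 of them among the 396. Here the score correlated with genotype at 0.47, so this fall too does not measure the share of choroid plexus.

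Of the hippocampal genes induced by glucocorticoids or stress 9 of 22 were higher (16 adjusted over the list alone), median 0.51 (adjusted p = 1.9e-10, adjusted p = 0.64 with an estimated correlation). Hif3a, a hypoxia-related transcription factor, rose by 1.22 ± 0.15 (adjusted p = 0.002), and Ddit4 by 0.70 ± 0.09 (adjusted p = 0.0022). Cholesterol biosynthesis genes had 6 of 23 lower (14 adjusted over the list alone), median -0.34 (adjusted p = 4.2e-09, adjusted p = 0.64 with an estimated correlation). Clustered protocadherins had a median of -0.39 with 1 of 54 higher and 1 lower (1 and 3 adjusted over the list alone, adjusted p = 1.6e-08, adjusted p = 0.64 with an estimated correlation). Synaptic genes had a median of -0.13 with 2 of 49 lower (4 adjusted over the list alone, adjusted p = 0.00016, adjusted p = 0.96 with an estimated correlation). Interferon response genes did not pass, with a median of -0.03 (adjusted p = 0.75). Blood markers had a median of -0.86 (adjusted p = 0.00058, adjusted p = 0.64 with an estimated correlation). Microglia markers had a median of -0.17 with 2 of 22 lower, also 2 adjusted over the list alone (adjusted p = 0.0057, adjusted p = 0.96 with an estimated correlation, and from 0.00012 to 0.38 with 1 library left out). Choroid plexus markers had a median of 0.98 that did not pass (adjusted p = 0.058), with Ttr at 490, 1700 and 45.3 CPM in Dnmt3a1-/- and 58.4, 84.5 and 69.6 CPM in wild type. Beside these list medians, reads outside genes were 9.69% to 10.3% of uniquely aligned reads in Dnmt3a1-/- hippocampus and 8.41% to 8.74% in wild type, and the 500 genes with the highest ratio of nuclei over cortex were higher by a median of 0.23 relative to all genes.

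**Figure D3:**
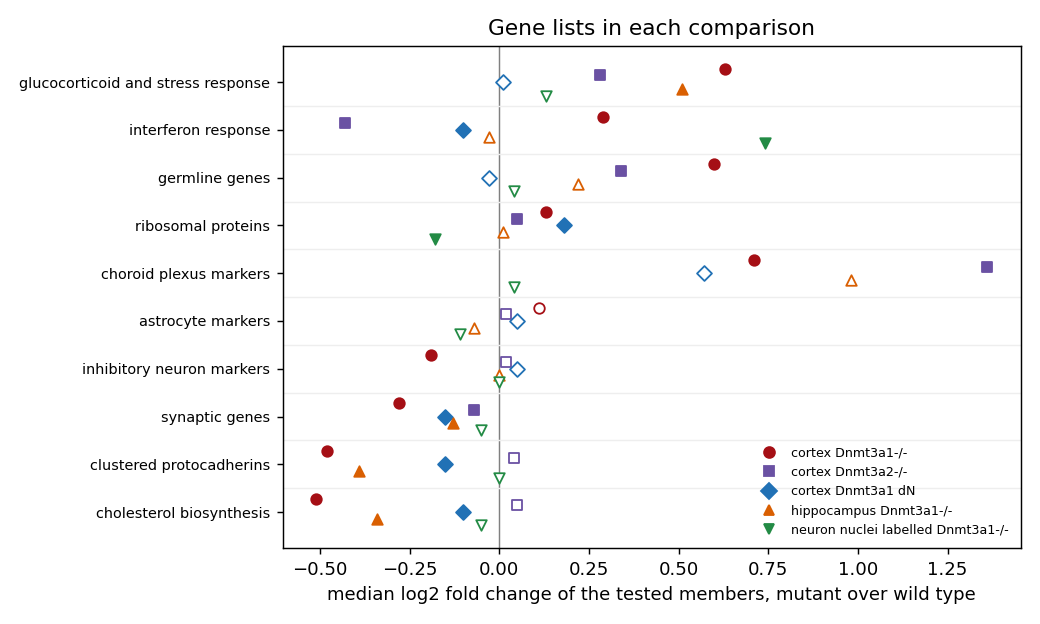
Median log2 fold change (x axis, mutant over wild type) of the tested members of 10 gene lists (y axis) in the 5 comparisons, filled where camera passed with the preset correlation. Cholesterol biosynthesis lies at -0.51 in cortex and -0.34 in hippocampus of Dnmt3a1-/- mice, and no list passed with an estimated correlation.

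Genes called in cortex Dnmt3a1-/- were followed as sets into hippocampus. Of 1335 genes higher in cortex 1260 (94.4%) were also higher in hippocampus, with a median of 0.28, and of 1378 lower genes 1289 (93.5%) were lower, with a median of -0.23. Camera gave p = 9.5e-44 and 2.8e-35, and p = 0.0034 and 0.023 with an estimated correlation. Both comparisons called 189 genes higher (22.5 in independent lists) and 97 lower (11.9 in independent lists), and 0 the opposite way. Same-numbered libraries of hippocampus and cortex shared deviations from their group means (correlations of 0.26, 0.135 and 0.216 in wild type and 0.082, 0.115 and 0.118 in Dnmt3a1-/-), so the 2 comparisons cannot be taken as independent, which the counts for independent lists leave out. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson's r = 0.68. The same sets leaned the same way in Dnmt3a1_delta_N, where 83.6% of the higher genes were higher and 89.3% of the lower genes were lower (camera across 1406 and 1414 genes, p = 9e-19 and 2.4e-31, and p = 0.064 and 0.016 with an estimated correlation). Their medians there were 0.12 and -0.13, against 0.45 and -0.37 in cortex Dnmt3a1-/- itself. In Dnmt3a2-/- the shares were 76.0% and 71.9% with medians of 0.09 and -0.05 (camera p = 7.7e-10 and 2.7e-07, and p = 0.049 and 0.16 with an estimated correlation).

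**Figure D4:**
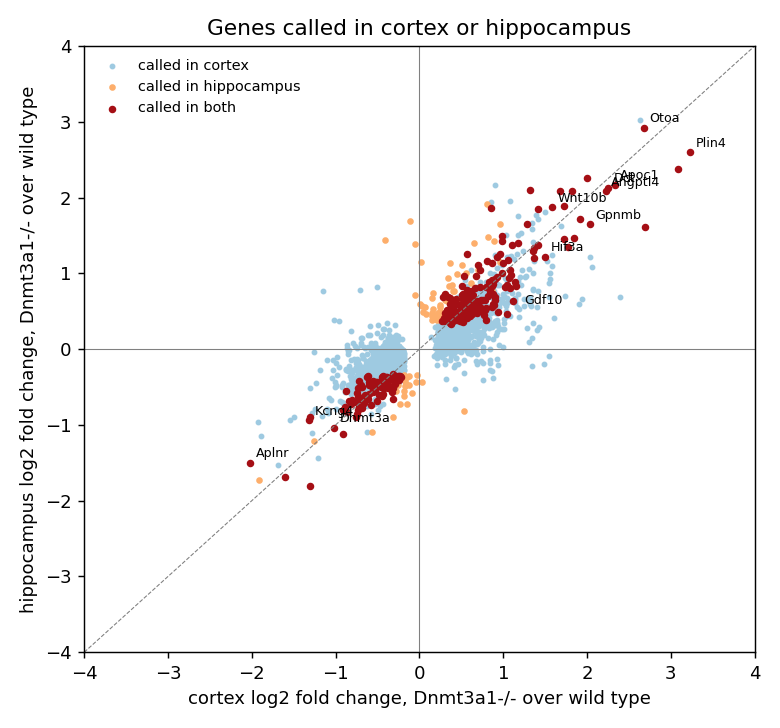
Log2 fold change in hippocampus (y axis) against cortex (x axis), Dnmt3a1-/- over wild type, for genes called in either tissue, with the line of equality dashed. The 189 genes called higher and the 97 called lower in both tissues lie in the same direction, and 0 genes were called in opposite directions.

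Neuron nuclei labelled Dnmt3a1-/- were compared with wild type nuclei to look at neurons alone. Myo5c, an unconventional myosin, rose by 2.09 ± 0.14 on the log2 scale (SE, n = 2 against 2), from 16.9 to 71.8 CPM (adjusted p = 2.9e-06), and in cortex by 2.06 ± 0.24 (n = 3 against 3, adjusted p = 0.00068). Got1l1, related to aspartate aminotransferase, rose by 2.73 ± 0.37 (adjusted p = 0.0039), Rnf213, a ubiquitin ligase, by 1.77 ± 0.28 (adjusted p = 0.012), and Crb2, a polarity protein, by 1.31 ± 0.19 (adjusted p = 0.0076). Ighm, an immunoglobulin chain, fell by 2.23 ± 0.23 (adjusted p = 0.00057). Mab21l1, Got1l1, Ppm1m, Crb2 and Med12, listed after their values were seen, were among the genes called higher in cortex, hippocampus and these nuclei. Of them Mab21l1, a developmental gene, had log2 fold changes of 3.09, 2.37 and 2.85, and Med12, a subunit of Mediator, of 0.57, 0.50 and 0.83.

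Of 15860 genes in nuclei 39 were called by edgeR, 34 higher and 5 lower, 1425 had an unadjusted p under 0.05, and DESeq2 called 80. With the replicate number as a block, not taken as pairs here, 740 were called, 452 higher and 288 lower. Without wild type nuclei library 1 the count was 4, without the first nuclei library labelled Dnmt3a1-/- 87 and without the second 364. Of the genes higher in cortex Dnmt3a1-/- 74.0% were higher in these nuclei, and of the lower genes 69.8% were lower (camera p = 3.2e-10 and 2e-04, and p = 0.25 and 0.53 with an estimated correlation). Both comparisons called 17 genes higher (2.85 in independent lists), 1 lower (0.478 in independent lists) and 0 the opposite way. Interferon response genes had a median of 0.74 with 9 of 25 higher adjusted over the list alone and 0 called by edgeR over all genes (adjusted p = 2.8e-06, adjusted p = 0.96 with an estimated correlation). Blood markers had a median of -1.14 with 1 of 6 lower and 4 adjusted over the list alone (adjusted p = 2.8e-06, adjusted p = 0.96 with an estimated correlation). Mitochondrially encoded genes had a median of -0.69 with 6 of 6 lower adjusted over the list alone (adjusted p = 0.00027, adjusted p = 0.96 with an estimated correlation). The lists of ribosomal protein genes and nuclear genes of oxidative phosphorylation had medians of -0.18 and -0.19, with 0 of 72 and 0 of 62 members called over all genes or over the list alone (adjusted p = 2e-07 and 2.6e-05, each adjusted p = 0.96 with an estimated correlation), and missed the threshold without wild type nuclei library 2 (adjusted p = 0.094 and 0.089, from 4.4e-14 and 9.4e-07 upward with other libraries left out). Immediate early genes had a median of 0.37 (adjusted p = 1e-06, adjusted p = 0.96 with an estimated correlation), with adjusted p = 0.39 without wild type nuclei library 1. Striatum markers had a median of 0.16 with 0 of 20 called (adjusted p = 0.025, adjusted p = 0.96 with an estimated correlation, and from 0.00055 to 0.59 with 1 library left out). Cholesterol biosynthesis genes did not pass in nuclei, with a median of -0.05 (adjusted p = 0.52).

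The effects of the mutations were compared directly as differences of log2 fold changes. Between Dnmt3a1_delta_N and Dnmt3a1-/- in cortex 17 genes differed, 3 higher and 14 lower in the former's effect, and 479 with the replicate number as a block. Dnmt3a itself differed by 0.85 ± 0.1 (adjusted p = 0.0026), and Ddit4 by -0.92 ± 0.13 (adjusted p = 0.0089). Between Dnmt3a2-/- and Dnmt3a1-/- 34 genes differed, 20 higher and 14 lower (294 with the block), among them Angptl4 by -2.17 ± 0.29 and Kcng4 by 1.26 ± 0.17 (adjusted p = 0.0054 for both). Between nuclei labelled Dnmt3a1-/- and cortex 59 genes differed, 41 higher and 18 lower (900 with the block), among them Mt2 by -1.45 ± 0.16 (adjusted p = 0.0013). Between hippocampus and cortex 0 of 15433 genes differed by edgeR, with a lowest adjusted p of 0.24, and DESeq2 called 3. There 777 genes had an unadjusted p under 0.05 by edgeR, near the share that chance gives. The count of 17 was 184, 8 or 9 without Dnmt3a1_delta_N library 1, 2 or 3, 6 or 5 without wild type n library 1 or 3, 8, 4 or 9 without Dnmt3a1-/- library 1, 2 or 3 and 5 or 7 without plain wild type library 2 or 3. The count of 34 was 87 without Dnmt3a2-/- library 2, 0 without wild type r library 2 and 19, 11 or 64 without Dnmt3a1-/- library 1, 2 or 3. The count of 59 was 93 without the first mutant-labelled nuclei library, 115 without wild type nuclei library 2, 21 or 17 without cortex Dnmt3a1-/- library 1 or 2 and 16 or 18 without plain wild type library 2 or 3.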

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

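The 4 gene lists compared between effects below, the test of astrocyte markers, the nuclei scored by genes higher in both tissues and the splits with a block were chosen after the results were seen, and the choroid plexus score as a covariate was added after the data were seen; the other tests were planned.

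A test of the difference between effects singled out 17 genes between Dnmt3a1_delta_N and Dnmt3a1-/- in cortex, each effect taken against its own wild type series. The difference of log2 fold changes was 0.85 for Dnmt3a, 0.59 for Nectin3 and 0.63 for Kcnj10, and -0.89 for Mrpl41, -0.68 for Scara3, -0.92 for Thbs4, -0.92 for Ddit4 and -1.17 for Acacb (edgeR adjusted p between 0.0026 and 0.044). List medians of the difference were -0.62 for genes induced by glucocorticoids or stress, -0.48 for interferon response genes, 0.12 for synaptic genes and 0.45 for cholesterol biosynthesis genes (camera adjusted p = 8.7e-10, 6e-09, 0.00045 and 2.4e-15, and 0.26, 0.26, 0.6 and 0.26 with an estimated correlation). Of 25 splits of the libraries 2, the real one included, gave at least 17 genes. The other, with 655, kept the real arrangement of the Dnmt3a1-/- set and so held its effect, and the rest gave 0, so these splits do not settle whether chance gives 17.

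Between Dnmt3a2-/- and Dnmt3a1-/- in cortex 34 genes differed. The differences were 0.90 for Dnmt3a, 1.26 for Kcng4, 0.71 for Sqle, 0.92 for Frzb and 0.83 for Msmo1, and -1.34 for Cep128, -2.17 for Angptl4, -1.06 for Gdf10, -2.31 for Dct and -0.88 for Plch2 (edgeR adjusted p between 0.0054 and 0.014). List medians of the difference were -0.36 for genes induced by glucocorticoids or stress, -0.78 for interferon response genes, 0.22 for synaptic genes and 0.54 for cholesterol biosynthesis genes (camera adjusted p = 3.1e-05, 2e-07, 8.7e-06 and 1.1e-18, and 0.52, 0.55, 0.52 and 0.056 with an estimated correlation).

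Between the nuclei labelled Dnmt3a1-/- and cortex 59 genes differed. The differences were 0.93 for Dnmt3a, 2.03 for Kcnk9, 1.02 for Nwd1, 1.12 for Shc3 and 0.84 for Vps13c, and -1.45 for Mt2, -1.46 for Gdf10, -1.76 for Hif3a, -3.22 for Pmaip1 and -1.5 for Acacb (edgeR adjusted p between 0.0013 and 0.022). List medians of the difference were -0.64 for genes induced by glucocorticoids or stress, 0.19 for synaptic genes and 0.38 for cholesterol biosynthesis genes (camera adjusted p = 4.4e-07, 2e-06 and 1.1e-08, and 0.27, 0.49 and 0.27 with an estimated correlation), while interferon response genes, at 0.23, did not pass (camera adjusted p = 0.39). Of 32 lists tested for each of these differences 13 passed with Dnmt3a1_delta_N, 14 with Dnmt3a2-/- and 13 with nuclei, and 0 with an estimated correlation. Between hippocampus and cortex 14 of 32 passed, again 0 with an estimated correlation, ribosomal protein genes with the lowest adjusted p (median -0.14, camera adjusted p = 4.3e-08, and 0.74 with an estimated correlation). Of the 4 lists followed here 3 passed: -0.36 for interferon response, 0.13 for synaptic and 0.13 for cholesterol biosynthesis genes (camera adjusted p = 1.1e-06, 0.00049 and 0.032, and 0.53, 0.74 and 0.84 with an estimated correlation), while genes induced by glucocorticoids or stress, at -0.13, did not (camera adjusted p = 0.19). For single genes between hippocampus and cortex the real count was 0, which 25 of 25 splits reach by necessity, so they test nothing. The highest other count was 179, in a split that kept the real cortex arrangement.

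Other splits of the 6 libraries were too few for a share under 0.05 in cortex and hippocampus. The real cortex Dnmt3a1-/- split gave 2845 genes (1 of 10 splits as high, highest other 0), the hippocampus split 396 (1 of 10, highest other 0), and the Dnmt3a1_delta_N split 0 (highest other 10), which 10 of 10 splits reach by necessity. These fits left the pairing out. Fitted with the replicate number as a block, the real split gave 4941 genes in Dnmt3a1-/- and 33 higher and 86 lower in Dnmt3a1_delta_N, and the 3 other splits that part all 3 pairs gave 0 each. Each other split mixes mutants and wild types within a group, so a real effect widens the spread there and lowers the count. Their low counts therefore do not show what libraries without an effect would give. The split of the plain from the n wild type series gave 3199 genes (1 of 10, highest other 0).

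Genes induced by glucocorticoids or stress were higher in cortex and hippocampus of Dnmt3a1-/- mice, with medians of 0.63 (95% bootstrap interval 0.37 to 0.94) and 0.51 (0.35 to 0.83), 11 of 23 and 9 of 22 members called, and list calls lost with an estimated correlation (adjusted p = 0.38 and 0.64). All intervals here come from resampling the genes of a list, not the libraries, so they do not measure the spread between libraries. Choroid plexus tissue carried along in dissection was tested with its marker score as a covariate. The medians were then 0.85 (0.49 to 0.98) and 0.54 (0.39 to 0.84) and did not fall. For these libraries this argues against it as the whole source, although the score correlated with genotype at 0.68 and 0.47. A larger share of astrocytes was tested with their markers, whose medians of 0.11 (-0.03 to 0.20) and -0.07 (-0.18 to 0.14) lay below those of the list. A stress response of the animals before tissue was taken and a direct effect of the mutation were not tested and stay open.

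The Dnmt3a count in the nuclei labelled Dnmt3a1-/- lay little below wild type (381 and 371 against 409 and 395 CPM) and did not pass, and a mislabelled sample could give this. Scored by the genes called in cortex Dnmt3a1-/-, the labelled mutants stood at -0.482 and -0.796 and the wild types at -0.798 and -1.029, a gap of 0.002 that decides nothing alone. The 20 genes called at least 2-fold higher in both cortex and hippocampus had mean log2 CPM of 2.04 and 1.77 against 1.06 and 1.09, a gap of 0.68 beside a largest range of 0.27 within a group, which argues against a swap and against a wrong label of a single library. Their median log2 fold change was 0.64 in nuclei and 1.63 in cortex, so nuclei of mixed genotype, or an effect that differs between cell types, stay open. Transcripts of the locus that stay in nuclei were not tested.

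Reads outside annotated genes, not used in any comparison, made up at least 10.34% of uniquely aligned reads in cortex Dnmt3a1-/- and 9.69% in hippocampus Dnmt3a1-/-, above the highest wild type value of 10.16% and 8.74%. Genomic DNA in the mutant libraries was tested with olfactory receptor genes, whose log2 ratios of -0.06 (2 SE 0.25) and -0.01 (2 SE 0.23) do not decide. More nuclear RNA was tested with the 500 genes with the highest ratio of wild type nuclei over wild type cortex. They were higher by 0.29 (0.26 to 0.32) in cortex and 0.23 (0.19 to 0.25) in hippocampus. The values were 0.07 in Dnmt3a2-/-, 0.08 in Dnmt3a1_delta_N and -0.06 (-0.09 to -0.03) in nuclei labelled Dnmt3a1-/-. These intervals resample genes, not libraries. The libraries that chose the genes were also controls, which alone shifts cortex values up and the nuclei value down. The hippocampus libraries did not choose the genes, and the value there goes with more nuclear RNA. It is not fully free of the shift, however. Same-numbered wild type libraries of hippocampus and cortex shared deviations (correlations of 0.26, 0.135 and 0.216), and those cortex libraries helped to choose the genes. In cortex 0.29 lay above the 0.07 and 0.08 that share the shift. Genes rich in nuclei are also rich in neurons, but a general rise of neuronal genes goes against the medians of synaptic genes, inhibitory and excitatory neuron markers in cortex (-0.28, -0.19 and -0.13). In hippocampus these medians (-0.13, 0 and -0.03) weigh little against it, so it stays open there. Changed expression of the 500 genes themselves stays open in both tissues. The -0.06 in nuclei does not decide it, since selection shifts that value down and the genotype of those nuclei is unsettled.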

How the results depend on the processing

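The choroid plexus score and the crossed pairs were chosen after the data were seen; the other alternatives were planned.

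DESeq2 size factors kept all 9 counts of genes within 1.5 times, and a mean CPM of at least 1 kept all 5 it was run on. The 1.5-fold minimum, fewer genes by construction, gave 743 in cortex Dnmt3a1-/- and 204 in hippocampus. For the other changes the cause was not tested. The Wald test of DESeq2 gave 8 in Dnmt3a2-/-, 31 in Dnmt3a1_delta_N, 597 in hippocampus, 80 in nuclei, and 101, 175, 3 and 296 for the differences of effects (Dnmt3a1_delta_N, Dnmt3a2-/-, hippocampus and nuclei, each against cortex Dnmt3a1-/-). No filter beyond 1 count gave 64, 17, 1039 and 243, and 67, 591, 3 and 619. The replicate block gave 4941 in cortex Dnmt3a1-/-, 55 in Dnmt3a2-/-, 33 higher and 86 lower in Dnmt3a1_delta_N (1.2e+02 in all), 246 in hippocampus and 740 in nuclei, and 479, 294 and 900 for the differences with Dnmt3a1_delta_N, Dnmt3a2-/- and nuclei. Sex as a term gave 55 in Dnmt3a2-/-, 1 in Dnmt3a1_delta_N and 740 in nuclei; with 2 libraries per group it is the block. All 8 wild type libraries gave 2 in Dnmt3a2-/-, without Rps4l (adjusted p = 0.28, from 5.4e-22 to 0.28 over the alternatives), and crossed pairs gave 2. The choroid plexus score gave 434 in cortex Dnmt3a1-/-, 13 in Dnmt3a2-/- and 202 in hippocampus.

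Leaving out 1 library gave 1599 to 2725 genes in cortex Dnmt3a1-/-, 25 to 139 in Dnmt3a2-/-, 0 to 2 in Dnmt3a1_delta_N, 86 to 783 in hippocampus and 4 to 364 in nuclei, and for the differences of effects 4 to 184, 0 to 87, 0 throughout and 16 to 115, the lone library of a pair being assumed to vary like the others. Of the sets of genes called in cortex Dnmt3a1-/-, an estimated correlation ended the call of the lower genes in Dnmt3a2-/- (p = 0.16 across 1418 genes), the higher genes in Dnmt3a1_delta_N (p = 0.064 across 1406 genes) and both in nuclei (p = 0.25 and 0.53 across 1330 and 1383 genes).

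Of the genes named, the replicate block kept 203 results on their side of the threshold, ended 20 and added 6. The DESeq2 Wald test kept 217, ended 6 and added 6. Sex as a term kept 184, ended 16 and added 1. Some calls of named genes also ended with 1 library left out. The choroid plexus score kept 100 and ended 86. All 8 wild type libraries kept 98 and ended 30, while Ptprz1 (0.03) and Col1a1 (0.01) changed sign in cortex Dnmt3a1-/-. That fit has no term for the wild type series, so a lost call there is not shown to be false. Of the 54 list calls the block kept 51. Lists reversed without 1 library, with the range of adjusted p over the libraries left out, were in Dnmt3a2-/- excitatory neurons (0.00062 to 0.72), choroid plexus (2.9e-13 to 0.81, reversed at 0.61) and ribosomal proteins (2.8e-07 to 0.62, reversed at 0.15) without mutant library 2, immediate early genes (1.3e-07 to 0.64) without mutant library 1 and interferon response (6e-57 to 0.17, reversed at 8.5e-06) without wild type r library 2, and in Dnmt3a1_delta_N mitochondrially encoded genes (0.002 to 0.82) without mutant library 3.

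A trend with gene length was not run. Simulated recovery of 1.5-fold changes was 23.9% in nuclei, with 25.3 to 39.0 M counts per library, and 65.7% in hippocampus, with 8.7 to 23.2 M, so depth alone did not set it.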

Other observations

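No test of this part was chosen after its result was seen.

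The 3 wild type cortex series differed by 5368 genes (plain against r, 16137 tested), 3199 (plain against n, 15940 tested) and 4409 (r against n, 16179 tested). Each count was above those between a mutant and its own series in cortex (2845, 1 and 0) when fitted without pairing. With the replicate number as a block Dnmt3a1-/- gave 4941, from a fit of another form that cannot be ranked against the counts between series. The labels give no batch for these series.

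Counts of the HOX cluster genes were 1 to 13 per library in all 26 libraries. The highest, 13, was in a wild type library of the n series.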
